A study of Homo sapiens with 16 samples.

How the data were processed

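Cells of 4 labelled populations from a human episomal induced pluripotent stem cell line were encapsulated and made into libraries with 10x Genomics chemistry, per the labels' protocols. The 16 GEO samples are 4 sequencing lanes of each of 4 libraries, so lanes are repeat runs of 1 library and not replicates. Differentiations used cells within 15 passages of thawing. Cell Ranger and the genome build GRCh38 are named in the submitters' processing notes; the version, the annotation release, the cell calling settings and any equalising of depth between libraries are not given in the sources used here. The deposited values are raw UMI counts per gene and barcode, per the file headers a matrix of whole numbers for 33694 genes and 1563 barcodes, pooled over 4 libraries that only a number after the barcode tells apart. Cell Ranger counts reads near one end of the transcript and collapses those with the same UMI, so a count is a captured molecule, gene length has little influence, and genes with near-identical copies can lose or swap counts.

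The following choices were made before the data were examined: the rule for tying barcodes to populations, the cell filter, the gene lists, the contrasts, the rule for named genes and the alternatives in the closing section, except those said there to have been added. A barcode suffix was to be tied to a labelled population only by a file that names it or by barcode numbers equal to those stated in the series text. Neither was the case, since 331, 391, 154 and 687 barcodes stood against 329, 62, 213 and 162 stated cells, so all contrasts between labelled populations were left out. The series text speaks of fewer populations than it lists, and its total of 766 cells lies below the 1563 barcodes; which filter led from one to the other is not given in the sources used here. In place of the populations, cells were compared by transcripts: G2/M against G1 phase, CDC20 UMI against none among G2/M cells, and SPG20 UMI against none among G2/M cells with a CDC20 UMI. These classes rest on transcripts and are not the labelled populations. Whether those were set by proteins, reporters or transcripts is not given in the sources used here.

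Barcodes with at least 500 detected genes were kept, which removed 0 of 1563. No maximum was set for the mitochondrial share, which exceeded 25% in 5 cells, all in library 3. Doublets were called per library with Scrublet in scanpy 1.11.5, which marked 26 cells (1.66%), and were removed only in an alternative. Ribosomal protein genes took 35.4% of UMIs, mitochondrial genes 3.36%, MALAT1 2.99% and the 10 most abundant genes 11.1%. Counts were scaled to 10000 per cell and log-transformed for clustering on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2, resolution 0.5). A cluster was called like a cell type only if at least 3 of that type's markers were detected at 10 CPM or more and at least 2 were among its 10 leading genes by fold, with no marker of another type among these 10. The design restricted contrasts to cardiomyocyte-like cells; since no cluster was cardiomyocyte-like, all cells were used. Cell cycle phase came from scanpy's scores for fixed lists of 43 S-phase and 54 G2/M genes. Shares of cells with a UMI were taken after thinning every cell to 9400 UMIs, the 10th percentile of depth, which left out 151 cells.

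For each contrast, UMIs were summed over the cells of each class and divided by the class total to give CPM, and ratios were given with exact conditional binomial 95% intervals. Log2 ratios carry a pseudocount of 0.5 UMIs on each side. Shares carry exact Clopper-Pearson intervals, and single levels exact Poisson intervals. For 0 UMIs the level allowed by 3 counts is given. These cover counting error only. No p-values were computed, since each population had 1 library and cells are not replicates. The number of cells expected without a UMI of CDC20 or SPG20 was computed from each cell's depth and one common share of UMIs, after results were seen. For CDC20 it was 10.5 of 887 cells, against 56 found. Values per library were computed where a library had at least 20 cells in both classes, which held for library 4 in the first contrast, library 3 in the second and libraries 1 to 3 in the third. There were 10660, 10353 and 10284 genes with at least 100 UMIs over both classes. A list's median over such genes was set against 10000 random lists of the same size matched on expression, and its interval came from 500 Poisson draws of the counts. Lists with fewer than 3 such genes got no median, which left out the endothelial, epicardial, endoderm, immune, ventricular and atrial lists. The markers included 1 gene, ESRG, that the matrix lacked. Genes that define a contrast were left out of its lists: both phase lists in the first, CDC20 in the second, CDC20 and SPG20 in the third.

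Named genes were, per contrast, the 10 with the largest and the 10 with the smallest ratio among genes with at least 100 UMIs, at least 20 CPM in the higher class, an interval excluding 1 and the same direction in each library with at least 20 cells per class. Up to 4 members with the largest absolute ratio were available from every list, and 13 genes including CDC20, SPG20, MKI67, TNNT2, MYH6, MYH7 and BORA were always looked up. MYH6 and MYH7 had 0 UMIs in both classes of each contrast, so no ratio is given. Lists of neural progenitor, hindbrain, forebrain, neuron and actin-regulated genes and of housekeeping genes were added after the marker levels had been seen. The 6 housekeeping genes, among them ACTB at 4831 CPM and GAPDH at 3672 CPM, served as a check of gene names.

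The procedure was tested on counts simulated from the real class totals, with 200 genes changed by known folds. The simulated counts held counting error only, as the intervals assume, so variation between cells or libraries was not tested. Intervals covered the true ratio for 95.9%, 96.2% and 95.6% of unchanged genes in the phase, CDC20 and SPG20 contrasts and for 96.5%, 95.5% and 93.5% of changed genes. A 2-fold change excluded a ratio of 1 for 90%, 75% and 100% of genes, and a 1.5-fold change for 73%, 47% and 94%. In the first calculation of the alternatives the 100-UMI minimum was applied again within each subset of cells, so that lists lost members. This was noticed from the values, and members were then held at those of the reported result.

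Gene positions are from GENCODE 29 on GRCh38, matched by gene identifier. Alternatives covered the cell filter, mitochondrial share, doublets, cluster resolution, clustering without phase genes, thinning, the mean of cells' CPM, CPM without mitochondrial and ribosomal protein genes, each library left out, no minimum of UMIs and cells of every phase. Software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.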

Results

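Single-cell transcript counts were deposited for cells of a human episomal induced pluripotent stem cell line, a line reprogrammed with plasmids that do not integrate into the genome. The culture protocol describes a small-molecule cardiac differentiation, with the GSK3 inhibitor CHIR99021 at 6 µM on days 0 to 1 and the Wnt inhibitor IWR1 at 5 µM on days 4 to 5, after which contraction was seen on days 7 to 8. The labels name 4 populations, each run on 4 sequencing lanes. One is a G1 population negative for CDC20 and SPG20. The other 3 are in G2/M: negative for both, positive for CDC20 alone, or positive for both. CDC20 is the co-activator that directs the anaphase-promoting complex to its mitotic substrates, and SPG20 encodes spartin, a protein found at the midbody during cytokinesis. The design addresses how cycling cells positive for either gene differ from those negative for both. How cells were assigned to the populations is not given in the sources used here.

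The series text states 329, 62, 213 and 162 cells for the 4 populations, 766 in all. The deposited matrix held 1563 barcodes with 4 suffixes, of 331, 391, 154 and 687 barcodes, which are called libraries 1 to 4 here. None of these equals a stated number and no file names the suffixes, so the libraries were left unlabelled and the labelled populations were not compared. The 4 libraries held 15137111, 15602055, 4561632 and 15574184 unique molecular identifiers (UMIs, tags that count each captured transcript once). Median UMIs per cell were 38862, 35921, 33034 and 21508, median detected genes 5379, 5216, 5062.5 and 4122, and the median mitochondrial share 3.34%, 3.14%, 3.50% and 2.76%. There were no replicates of any population. Every interval below is a 95% interval of counting error only, and cells of a library are not replicates.

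The cells held almost no cardiac contractile transcripts and abundant neural progenitor transcripts. MYH6 and MYH7, the cardiac myosin heavy chains, and MYBPC3, cardiac myosin-binding protein C, had 0 of 50874982 UMIs, where 3 UMIs would be 0.0590 CPM (UMIs scaled to equal totals). The atrial light chain MYL7 had 4 UMIs, titin (TTN) 7, the Z-disc protein ACTN2 14, the calcium release channel RYR2 3 and phospholamban (PLN) 1. GATA4, TBX5 and TBX20, transcription factors of the cardiac lineage, had 0 UMIs each, and NKX2-5 had 36, or 0.708 CPM [0.496, 0.980]. Of the 16 cardiomyocyte markers, 12 lay under 1 CPM and 3 reached 10 CPM: TNNT2 (cardiac troponin T) at 13.9 CPM [12.9, 14.9], MYL4 at 16.8 CPM [15.7, 17.9] and ACTC1 (cardiac alpha-actin) at 34.0 CPM [32.4, 35.6]. TNNT2 lay between 12.4 and 16.5 CPM in the 4 libraries and MYL4 between 9.18 and 24.9 CPM, while ACTC1 stood at 79.9 CPM in library 2 and between 6.04 and 23.6 CPM in the others. Thinned to 9400 UMIs per cell, 10.7% of all cells had a TNNT2 UMI, against 11.8% [4.44, 23.9] of the neural-like cells described below, so its detection did not exceed that in cells that should lack it. Unthinned, the shares were 28.8% and 13.0% at median depths of 29246 and 13853 UMIs.

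All 6 neural markers were detected. SOX2, a transcription factor of pluripotent and neural stem cells, reached 315 CPM [310, 320], between 262 and 358 CPM in the libraries, with a UMI in 94.6% of cells. PAX6, a regulator of neural progenitors, stood at 54.4 CPM [52.4, 56.5], with a UMI in 52.2% of cells, and MAP2, a neuronal microtubule protein, at 123 CPM [120, 126]. Among progenitor genes listed after the data were seen, the intermediate filament gene NES stood at 416 CPM, TTYH1 at 348 CPM, SOX11 at 225 CPM and N-cadherin (CDH2) at 197 CPM. Of the 6 measured pluripotency genes, LIN28A (176 CPM) and DPPA4 (60.6 CPM) reached 10 CPM, while POU5F1 stood at 4.07 CPM and NANOG at 0.0983 CPM.

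**Figure D1:**
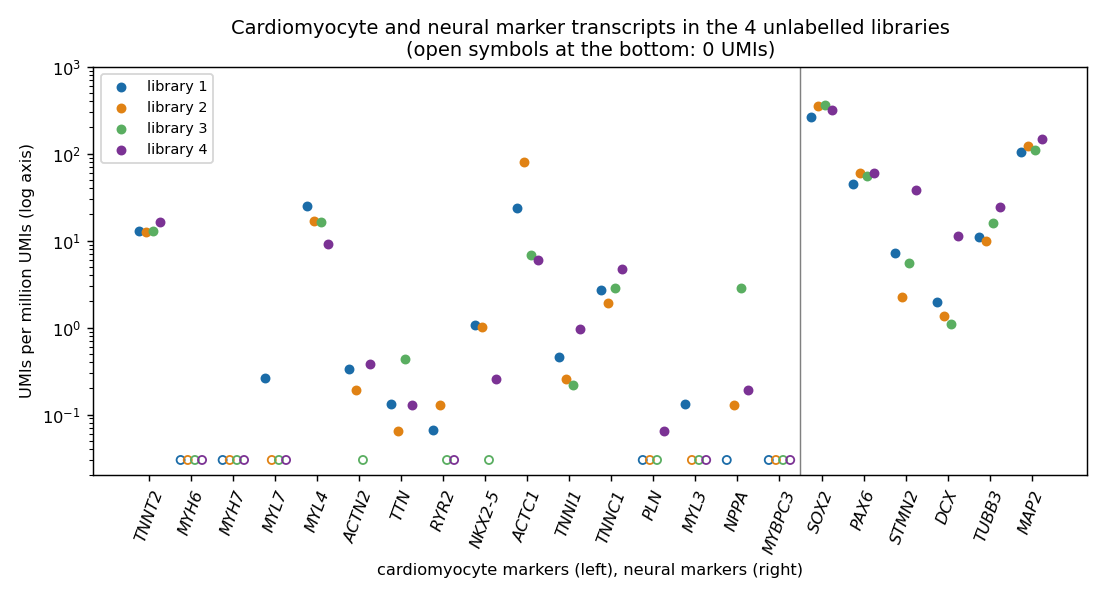
CPM (log axis) of 16 cardiomyocyte and 6 neural marker genes in each of the 4 unlabelled libraries, 1 point per library, with open symbols at the bottom for 0 UMIs. MYH6, MYH7 and MYBPC3 have 0 UMIs in all 4 libraries, while SOX2 lies between 262 and 358 CPM.

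Markers of other lineages were mostly low. The 8 epicardial markers were all under 1 CPM and summed to 0.590 CPM, the 10 endoderm and liver markers summed to 7.96 CPM, the 7 immune and blood markers to 5.29 CPM and the 10 endothelial markers to 47.1 CPM, of which EGFL7 gave 32.6 CPM and TEK 12.3 CPM. The 10 fibroblast markers summed to 137 CPM, mainly the matrix gene FBLN1 at 88.8 CPM. Smooth muscle markers were higher, with TAGLN (transgelin, an actin-binding protein) at 1170 CPM, RGS5 at 98.0 CPM and ACTA2 at 39.2 CPM, but MYH11, the smooth muscle myosin heavy chain, at 0.727 CPM. The 6 ventricular genes summed to 7.82 CPM, nearly all from LBH at 7.04 CPM, and the 13 atrial and nodal genes to 142 CPM, nearly all from the nuclear receptors NR2F2 (86.9 CPM) and NR2F1 (53.9 CPM).

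The 1563 cells fell into 8 clusters, 1 of which could be named from the markers. Cluster 6, of 69 cells (4.41% [3.45, 5.55] of cells, 67 of them from library 4), was neural-like, although at the finer cluster resolution of 1.0 only 0.896% of cells were: its leading genes included the neuropeptide gene SST, STMN2 (a neuronal microtubule regulator), ONECUT2, NHLH1, DLX2 and DCX (doublecortin of young neurons). No cluster was cardiomyocyte-like (0 of 1563 cells). Clusters 0 (315 cells, led by mitotic genes such as PIF1, DEPDC1 and CDK1) and 1 (305 cells, led by replication genes such as MCM6, UNG and PCNA) followed the cell cycle. Cluster 2, of 246 cells, had a median of 9687 UMIs, a median mitochondrial share of 5.66% and MT-ATP8, MT-ND4L and SNHG25 as leading genes. The leading genes of cluster 3 (216 cells) included HOXB2, a gene of the posterior neural tube, beside NR2F1, PAX6 and others. Those of cluster 5 (161 cells) included EGR2, a hindbrain gene, beside RGS5 and others. Cluster 7 (52 cells) had HESX1, FEZF1, LHX5 and OTX2, genes of the anterior neural plate, among its leading genes. Cluster 4, of 199 cells, was led by EDN1, SPP1, ACTC1, ANXA1 and ANKRD1. With no cardiomyocyte-like cluster, the contrasts below used all cells.

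Transcript-based cell cycle calls put 266 of 1563 cells in G1, 410 in S (26.2%) and 887 in G2/M (56.7%). The G2/M share was 97.3%, 94.4% and 94.8% in libraries 1 to 3 and 7.28% in library 4, where 36.5% were called G1 and 56.2% S. At 9400 UMIs per cell the G2/M shares were 90.2%, 89.4%, 91.5% and 4.46%, with 6, 4, 37 and 104 shallower cells left out. The phases are ranges of 2 scores, and 149 cells (9.53%) lay within 0.05 of a boundary. The labels divide the populations by cell cycle stage, which can set these shares, and RNA from the fluid around the cells was not estimated, so cycling is not read from them.

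**Figure D2:**
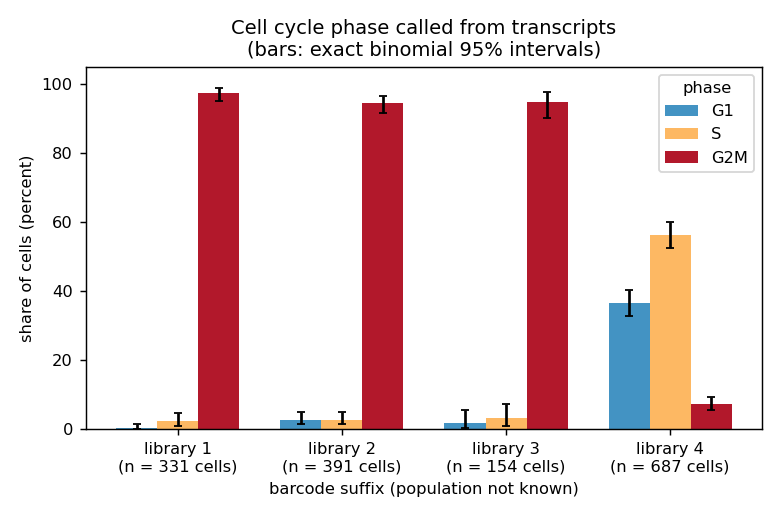
Share of cells (percent) called G1, S or G2/M from transcripts in each unlabelled library, with exact binomial 95% intervals as bars and the number of cells under each library. Libraries 1 to 3 have G2/M shares of 94.4% to 97.3% and library 4 of 7.28%.

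SPG20 transcripts did not peak in G2/M cells, while those of CDC20, itself 1 of the 54 genes behind the G2/M calls, did. CDC20 (ENSG00000117399, protein coding, chromosome 1, 43358955 to 43363203, plus strand, GRCh38) stood at 274 CPM [268, 279] in G2/M cells, 26.5 CPM [23.5, 29.8] in S and 24.4 CPM in G1. SPG20 (ENSG00000133104, SPART in GENCODE 29, protein coding, chromosome 13, 36301638 to 36370180, minus strand) stood at 30.5 CPM [28.7, 32.4] in G2/M, 52.9 CPM [48.6, 57.4] in S and 32.8 CPM [27.7, 38.6] in G1. Within library 4, which held most of the S and G1 cells, SPG20 was at 40.5 CPM [30.3, 53.2], 53.6 CPM [49.2, 58.3] and 32.6 CPM [27.3, 38.6] in the same phases. At 9400 UMIs, 54.0% [51.3, 56.6] of cells had a CDC20 UMI and 28.8% [26.5, 31.3] an SPG20 UMI, against 9.80% [3.26, 21.4] and 19.6% [9.82, 33.1] of the neural-like cells. The proliferation markers MKI67 and TOP2A were detected in 48.7% and 63.6%. Without thinning, the 4 shares were 66.0%, 59.1%, 65.1% and 71.5%.

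Cells called G2/M differed from cells called G1 by mitotic and cytokinesis genes on one side and neuronal genes on the other. This contrast of 887 with 266 cells mirrors at the transcript level the G2/M and G1 populations of the labels. PLK1, the polo-like kinase of mitotic entry and exit, was 63.0-fold higher [35.9, 138] in G2/M cells (151 against 2.28 CPM), and DEPDC1 66.4-fold higher [31.3, 225] (83.2 against 1.14 CPM). Stathmin-like STMN2 was lower in G2/M cells, at 5.97 against 112 CPM (log2 ratio −4.22 [−4.46, −3.99]), as was the Notch ligand gene DLL1, at 25.3 against 212 CPM (−3.07 [−3.20, −2.93]). Within library 4, the source of most G1 cells, PLK1 was 4.21 [3.29, 5.40], DEPDC1 5.05, STMN2 −1.72 [−2.20, −1.29] and DLL1 −1.42 [−1.73, −1.13]. The rule for named genes required the same direction there. With counts of all libraries thinned to 9400 UMIs, PLK1 was 4.89 [3.99, 6.19], DEPDC1 5.02, STMN2 −5.73 [−6.55, −5.07], ONECUT2 −6.53, SNCG −6.07 and DLL1 −3.14. The intervals of SPG20 (−0.11 [−0.36, 0.16]), CDKN1A, the p21 inhibitor of cyclin-dependent kinases (0.09 [−0.43, 0.71]), and TNNT2 (−0.21 [−0.57, 0.20]) included 0.

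Of 14 measured genes of cytokinesis and the central spindle outside the phase lists, 13 were higher in G2/M cells, 8 of them by 1.5-fold or more, with a median log2 ratio of 2.88 [2.48, 3.22], above all 10000 random lists of matched expression. The phase lists that set the classes hold 6 further members of this list. The random lists matched expression only, so they do not test whether the 14 genes merely rise along with the phase genes. The cytokinesis list split into 2 sets. The kinesin KIF14 (5.31), the abscission protein gene CEP55 (4.91), RACGAP1 of the centralspindlin complex (4.67) and INCENP of the chromosomal passenger complex (4.23) were far higher, whereas RHOA (0.35), SEPT7 (0.18) and MYH10 (0.25), chosen after their values were seen, were within 1.5-fold, so the median describes the first set. Of 25 spindle checkpoint and anaphase-promoting complex genes, 24 were higher and 14 by 1.5-fold or more (median 1.11 [0.68, 1.67]), led by PLK1, cyclin A2 (CCNA2, 4.57), cyclin B1 (CCNB1, 4.21) and BUB1B (4.10). BORA, which helps Aurora A activate PLK1, stood at 26.8 against 2.28 CPM (3.49 [2.67, 4.62]). In contrast, 9 of 25 abscission and ESCRT genes were higher and 16 lower, with a median of −0.07 [−0.13, 0.03] and only VPS4A (0.86), an ESCRT disassembly ATPase, past 1.5-fold. The abscission median lay at percentile 0.41 of the random lists, which centred on 0.14. All 8 measured histone genes were higher (median 1.64 [1.31, 1.99]), with H2AFX at 177 against 21.6 CPM. The other genes with the largest higher ratios were PBK (5.42), KIFC1 (5.07), PIF1 (4.91), SPC25 (4.79), FAM72D (4.79) and SGOL1 (4.69). FAM72D has near-identical copies, so its counts are uncertain.

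All 6 neural markers had lower levels in G2/M cells (median −1.20 [−1.36, −1.07], below all random lists), 3 of them by 1.5-fold or more: STMN2, DCX (−3.98) and TUBB3 (−1.95). SOX2 was nearly equal, at 320 CPM [314, 326] in G2/M and 325 CPM [308, 342] in G1. Within library 4 SOX2 was higher in G2/M cells, at 478 CPM [441, 517] against 329 CPM [311, 347]. Among the genes with the smallest ratios were also MIR217HG (−4.63), SNCG (−4.49), RGS16 (−4.33), ONECUT2 (−4.04), GADD45G (−3.28), the metallothionein MT1E (−3.20) and ELAVL4 (−3.14), an RNA-binding protein of neurons. Within library 4 the ratios of these genes ran from −1.18 for ONECUT2 to −4.73 for MT1E. Their direction there was required by the rule for named genes, so it is no separate support. Of the 69 neural-like cells, 65 were called G1. Leading genes of their cluster include STMN2, DCX, RGS16, SNCG and ONECUT2, so leaving it out reduces these differences by construction. Without that cluster the neural median was −0.51 [−0.65, −0.20], STMN2 −1.13 [−1.70, −0.47], RGS16 −0.09, ONECUT2 −0.32, ELAVL4 −0.54, GADD45G −0.78, SNCG −1.54, MIR217HG −2.53, DLL1 −1.95 and DCX −0.78 [−1.79, 0.58]. Immediate early genes were mostly higher in G2/M cells (14 of 15, median 0.84 [0.63, 0.96]), among them KLF6 (1.45), IER3 (1.22) and the near-identical heat shock genes HSPA1A (1.22) and HSPA1B (1.36). Of 6 cardiac transcription factor genes with enough counts, 4 were lower (median −0.66 [−0.95, −0.41]), led by MEIS1 (−1.34), NR2F1 (−1.01) and MEIS2 (−0.99), which the nervous system expresses as well.

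The medians of the other lists were those for smooth muscle (0.97), natriuretic and stress (0.69), pluripotency (0.60), sarcomere (0.42), fibroblast (0.41), calcium and channel (0.35), cardiomyocyte (0.29), G1 cyclin and E2F (0.26), glycolysis (0.24), cell cycle inhibitor (0.23), Hippo and growth regulator (0.14), matrix (0.09), nuclear oxidative phosphorylation (0.09), fatty acid oxidation (0.06) and mitochondrially encoded genes (0.06), beside a median of all genes of 0.10. Some of these medians rested on few genes with enough counts. These were 4 of 16 cardiomyocyte genes (2 higher, 2 lower), 3 of 25 calcium and channel, 8 of 29 sarcomere and 4 of 7 smooth muscle genes. FOXM1, a transcription factor of mitotic genes, was at 29.1 against 2.28 CPM, and the antiproliferative gene BTG2 at 37.9 against 115 CPM. No test was run, since by the labels the 4 libraries are different populations and not replicates. Of the 266 G1 cells 251 came from library 4, and of the 887 G2/M cells only 50, and the median depth was 15400 against 36468 UMIs. Within library 4 the medians were 2.28 for cytokinesis, 0.39 for the spindle checkpoint, 1.09 for histones, −1.16 for neural and 0.48 for immediate early genes, but −0.06 for smooth muscle, −0.08 for natriuretic and stress genes, −0.06 for cardiomyocyte markers and 1.60 for pluripotency genes. Without library 4, which left 15 G1 cells, the neural median was −0.13 [−0.57, 0.37], STMN2 −0.14 [−2.06, 5.75], ONECUT2 −0.21, ELAVL4 −0.77, SNCG −0.88, GADD45G −1.73, RGS16 2.27 and MT1E 0.85, and the immediate early median 0.02 [−0.42, 0.32]. MIR217HG (−4.01 [−5.35, −1.90]), DCX (−3.01 [−4.43, −0.48]), DLL1 (−2.84 [−3.25, −2.36]) and GADD45G kept intervals below 0 without library 4. DEPDC1 (3.98), PBK (3.59), KIF14 (2.95), KIFC1 (2.88), PIF1 (2.74), CEP55 (1.79 [0.26, 5.16]) and BORA (1.60 [0.07, 4.97]) stayed higher without it, and SGOL1 was 5.86.

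Among G2/M cells, those with a CDC20 UMI (831 cells) held more of the other mitotic transcripts than those without (56 cells). The contrast mirrors at the transcript level the CDC20-positive and CDC20-negative populations of the labels. Of 53 genes of the G2/M list other than CDC20, 52 were higher and 44 by 1.5-fold or more, with a median log2 ratio of 0.91 [0.87, 1.07], above all random lists. Aurora kinase A (AURKA) stood at 129 against 25.6 CPM (2.30 [1.77, 2.96]), the spindle protein gene HMMR at 147 against 38.9 CPM (1.90 [1.46, 2.42]), BORA at 27.4 against 6.14 CPM (2.04 [1.03, 3.60]) and the centromeric histone CENPA at 103 against 28.7 CPM (1.82 [1.31, 2.44]). SPG20 stood at 30.5 CPM with and 30.7 CPM without a CDC20 UMI (−0.03 [−0.53, 0.56]). This interval is too wide to show that the levels were alike.

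Cytokinesis genes were higher in 18 of 20 cases (median 0.77 [0.55, 0.99]), with CDCA8 of the chromosomal passenger complex and the kinesin KIF4A both at 1.52. Of 28 spindle checkpoint genes 21 were higher (0.66 [0.45, 0.88]), with PLK1 at 1.63, securin (PTTG1) at 708 against 250 CPM and CCNB1 at 1.47. The S-phase list had a median of 0.00 [−0.04, 0.19], with 21 of 42 genes higher, and abscission genes one of 0.12 [−0.03, 0.24]. TRIM59 (2.68), FAM72D (2.65), the DNA repair gene XRCC4 (1.72), BIN1 (1.64) and the histone chaperone ASF1B (1.62) completed the genes with the largest higher ratios. All 13 mitochondrially encoded genes were lower in cells with a CDC20 UMI (median −0.69 [−0.71, −0.66]), 11 of them by 1.5-fold or more, with MT-ATP8 at 13.4 against 62.5 CPM and MT-ND4L at 134 against 424 CPM. The potassium channel gene KCNJ6 (−2.30), LINC00152 (−1.71), MTRNR2L12 (−1.64), the filamin gene FLNC (−1.60), P3H3 (−1.52), SNHG25 (−1.47), the peptide hormone gene ADM (−1.46) and DGCR8 of the microRNA processor (−1.42) were lower too. MTRNR2L12 resembles mitochondrial ribosomal RNA, so its counts are uncertain. ANKRD1 and NPPB, genes of the natriuretic and stress list, stood at 221 against 571 CPM (−1.37) and 32.0 against 122 CPM (−1.93), while that list's median was 0.04.

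Other medians in this contrast were 0.38 for immediate early genes, 0.37 for fibroblast, 0.24 for calcium and channel, 0.23 for glycolysis, 0.20 for cell cycle inhibitor, 0.16 for cardiomyocyte, 0.12 for neural, 0.08 for sarcomere and for cardiac transcription factor, 0.04 for G1 cyclin, 0.01 for nuclear oxidative phosphorylation, 0.00 for fatty acid oxidation, −0.11 for Hippo, −0.15 for smooth muscle, −0.21 for pluripotency and −0.38 for histone genes, with a median of all genes of 0.06. The cardiomyocyte median, with an interval of [−0.40, 0.70], and the calcium and channel median rested on 3 genes each, the sarcomere median on 7. Within library 3, the only one with 20 or more cells in both classes, the medians were 0.87 for the G2/M list, 0.79 for the spindle checkpoint, 0.46 for cytokinesis, 0.53 for the S-phase list and −1.71 for mitochondrial genes. Cells with a CDC20 UMI were deeper, at a median of 37297 against 13040 UMIs in all libraries together and 36528.5 against 7134 UMIs in library 3. With counts thinned to 9400 UMIs, which also moved cells between classes, the G2/M median was 0.54 [0.46, 0.60] and the mitochondrial median −0.10 [−0.12, −0.06]. Smaller on thinned counts were also PLK1 (1.07), TRIM59 (1.25), CENPA (0.72), HMMR (0.69), FAM72D (0.69) and AURKA (0.56 [0.28, 0.86]), while the intervals of BIN1 (0.61), BORA (0.41 [−0.20, 1.14]), XRCC4 (0.37) and ASF1B (0.15) included 0. Among the lower genes KCNJ6 (−1.33), FLNC (−1.06), MT-ATP8 (−0.73), ADM (−0.66) and MT-ND4L (−0.39) kept intervals below 0 there, which DGCR8 (−0.74), LINC00152 (−0.55), SNHG25 (−0.42), P3H3 (−0.26) and MTRNR2L12 (−0.01) did not. Unthinned, KCNJ6 was −0.84 [−1.76, 0.48] with a mitochondrial share of at most 25%, −0.91 [−1.84, 0.41] without doublets and −1.26 [−2.35, 0.34] without library 1. LINC00152 was −0.64 [−1.32, 0.23] on unthinned counts without library 1. Unthinned, the mitochondrial median was −0.14 [−0.16, −0.10] without library 3 and 0.08 [0.04, 0.12] without cluster 2. Without library 3, MT-ATP8 was −0.63 [−1.37, 0.34] and MT-ND4L −0.72 [−0.94, −0.47].

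Among G2/M cells with a CDC20 UMI, those with an SPG20 UMI (539 cells) and those without (292 cells) showed small differences. The contrast was meant to mirror at the transcript level the SPG20-positive and SPG20-negative populations. If every UMI of these 831 cells had the same chance of being SPG20, 280.4 cells would lack one, close to the 292 that did. The classes thus part cells mostly by chance and depth, and their likeness says little about cells with and without SPG20. Of 24 abscission and ESCRT genes other than SPG20, the group in which spartin has been studied, 14 were higher and 10 lower (median 0.03 [−0.02, 0.06]), and none differed by 1.5-fold. The G2/M list had a median of 0.09 [0.06, 0.10] with 46 of 53 genes higher, and the cytokinesis list of 0.08 [0.06, 0.13] with 19 of 20 higher, in both cases with no gene past 1.5-fold. CDC20 stood at 287 against 266 CPM (0.11 [0.04, 0.17]). The mitochondrially encoded genes were lower in all 13 cases (−0.20 [−0.22, −0.18]), with MT-ND4L at 121 against 167 CPM.

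The largest higher ratios belonged to SFRP4, a secreted Wnt antagonist, at 301 against 201 CPM (0.58 [0.51, 0.66]), FAM72D (0.47), the sorting nexin SNX1 (0.46), R3HDM1 (0.45), LNP1 (0.44), PLPP5 (0.44), MBOAT2 (0.43), C8orf58 (0.41), LPP (0.41) and LGI1 (0.39). The largest lower ratios belonged to osteopontin (SPP1) at 16.3 against 33.8 CPM (−1.05 [−1.27, −0.84]), MT-ND4L (−0.46), SNHG25 (−0.41), the phosphatase CDC25B (−0.38), ENO3 (−0.34), ZRSR2 (−0.33), NUDT6 (−0.33), PNCK (−0.32), MAGI1 (−0.32) and RMI1 (−0.31). G1 cyclin and E2F genes had a median of 0.15 [0.04, 0.22], with 12 of 15 higher and cyclin D1 (CCND1) at 0.28, and pluripotency genes one of −0.31 [−0.48, −0.13], with POU5F1 at 2.74 against 7.24 CPM (−1.40), the only list gene past 1.5-fold. In libraries 1, 2 and 3 the pluripotency median was −0.37, −0.39 and 0.18, that of the G2/M list 0.11, 0.07 and 0.09, of cytokinesis 0.03, 0.13 and 0.22, of abscission 0.02, 0.00 and 0.10, of G1 cyclins 0.04, 0.18 and 0.12 and of mitochondrial genes −0.12, −0.11 and −0.66. The medians of the smooth muscle (0.11), Hippo (0.07), neural (0.07), cardiomyocyte (0.06), sarcomere (0.06), matrix (0.06), fatty acid oxidation (0.06), spindle checkpoint (0.03), nuclear oxidative phosphorylation (0.03), histone (0.03), cardiac transcription factor (0.02), S-phase (0.01), calcium and channel (0.01), glycolysis (0.01), natriuretic and stress (0.01), cell cycle inhibitor (−0.02), immediate early (−0.04) and fibroblast (−0.09) genes stood beside a median of all genes of 0.04. The cardiomyocyte and the calcium and channel medians rested on 3 genes each, the sarcomere median on 7. Median depth was 39700 against 31183.5 UMIs. With counts thinned to 9400 UMIs the mitochondrial median was −0.07 [−0.09, −0.04] and the G2/M median 0.04 [0.01, 0.08]. SFRP4 stood at 0.19 [0.01, 0.36] and FAM72D at 0.92 [0.44, 1.37] on these counts, PLPP5 (0.17), LNP1 (0.11), LPP (0.01) and MBOAT2 (0.01) had intervals that included 0, and R3HDM1, LGI1, SPP1, SNHG25, ZRSR2 and PNCK changed sign with intervals that included 0. MT-ND4L stood at −0.24. The intervals of the other lower genes widened to include 0, with CDC25B at −0.63 [−1.37, 0.01], ENO3 at −0.67 [−1.47, 0.00], NUDT6 at −0.39, MAGI1 at −0.16 and RMI1 at −0.14. Unthinned, SFRP4 was 0.37 without library 1 and 0.87 without library 2, FAM72D 0.79 without library 2, SPP1 −2.02 without library 1 and −0.36 without library 2, and MT-ND4L −0.29 without library 3.

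**Figure D3:**
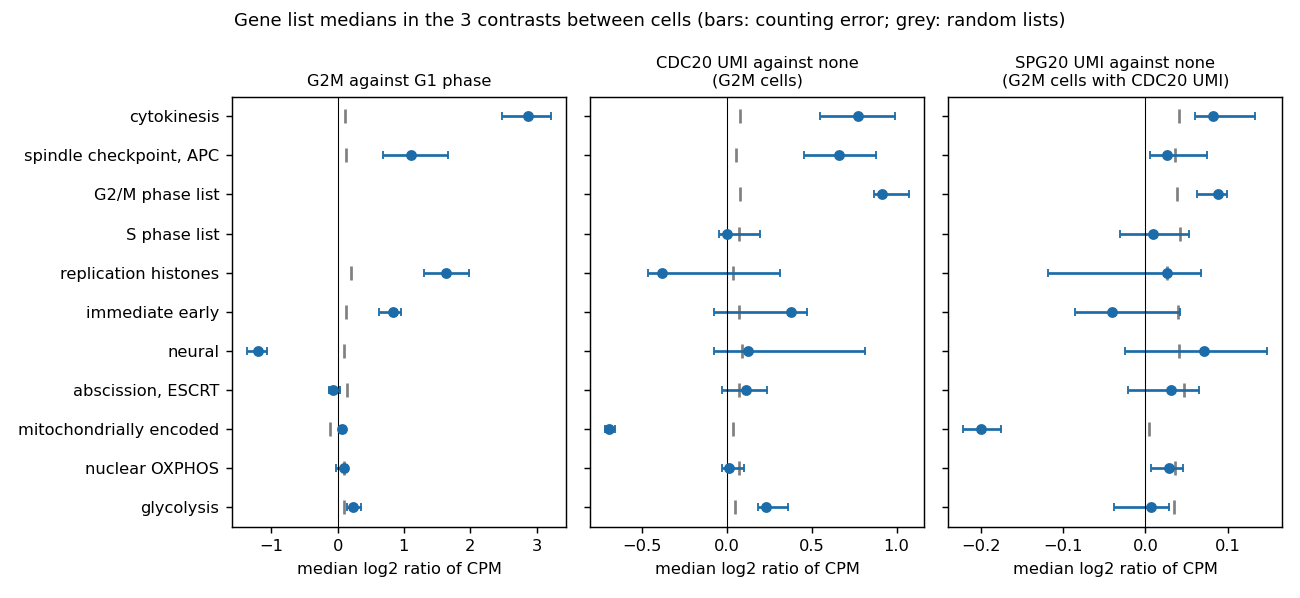
Median log2 ratio of CPM of 11 gene lists in the 3 contrasts between cells, with 95% intervals of counting error as bars, grey ticks for the median of random lists matched on expression, and a separate scale for each panel. The phase lists are left out of the first panel because they define its classes. Cytokinesis genes stand at 2.88, 0.77 and 0.08, and mitochondrially encoded genes at 0.06, −0.69 and −0.20.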

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

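Alternatives on subsets of cells (library 4 alone, without cluster 2 or 6, with and without thinning, and cells of at least 9400 UMIs) and on thinned counts without mitochondrial and ribosomal protein genes were chosen after results were seen, and the others before. A value counts as the same within the 95% interval of the reported value, and as moved outside it. Of the comparisons of main results 92 stayed the same, 56 moved and 1 changed sign; for named genes these numbers were 1001, 236 and 26. Causes were not tested. No fit with libraries as blocks was made, although both classes of each contrast occur in all 4 libraries. By the labels these are different populations and not replicates. Contrasts between labelled populations could not be run, the alternative of all cells became the main one, and cells with both TNNT2 and ACTN2 UMIs numbered 2. List members were held at those of the main result, a choice made after values were seen.

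The share of cardiomyocyte-like cells stayed at 0 in its 5 alternatives (1000 genes, mitochondrial share, doublets, resolution 1.0 and clusters without phase genes); at resolution 1.0 the neural-like share was 0.896%. Thinning also moved cells between phases and classes. On thinned counts G1 cells made up 12.9% and S cells 32.4%. Shares with a CDC20, SPG20, MKI67 and TOP2A UMI were 70.7%, 49.0%, 68.9% and 77.3% at 18600 UMIs and 66.0%, 59.1%, 65.1% and 71.5% without thinning, with 388 shallower cells left out at 18600 and none without thinning, so both the depth and the cells differ.

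In the phase contrast (G2/M against G1), library 4 alone gave 2.28 [1.20, 2.63] for cytokinesis and 0.48 for immediate early genes. The neural median was −0.51 without cluster 6 and −1.43 without cluster 2. With each library left out in turn, cytokinesis ranged from 2.37 (without library 4) to 2.95 (without 1), neural genes from −1.25 (without 3) to −0.13 (without 4) and immediate early genes from 0.0231 (without 4) to 1.03 (without 2). RGS16 ranged from −4.51 (without 2) to 2.27 (without 4) and MT1E from −4.07 (without 2) to 0.85 (without 4), the latter resting on 15 G1 cells.

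In the CDC20 contrast the G2/M median was 0.86 without doublets, 0.54 on thinned counts, 0.79 for the mean of cells' CPM, 0.85 without mitochondrial and ribosomal protein genes in the CPM, 0.53 without these genes on thinned counts, 0.54 without cluster 2 and thinned, 1.04 in cells of at least 9400 UMIs, and 2.14 for cells of every phase. The mitochondrial median was −0.63 with a mitochondrial share of at most 25%, −0.76 without doublets, −0.10 on thinned counts, −1.16 for the mean of cells' CPM, −0.75 without those genes in the CPM, −0.11 with thinning as well, −0.0467 for every phase, 0.0754 without cluster 2 and −0.0217 if thinned too, and −0.24 in cells of at least 9400 UMIs, with a range from −0.99 (without library 2) to −0.14 (without library 3). Signs changed for BIN1 (−0.0415), KCNJ6 (0.23), LINC00152 (0.54) and ADM (0.85) with every phase, for MT-ATP8 (0.93) and SNHG25 (0.31) without cluster 2, and for MTRNR2L12 (0.44) when thinned too.

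In the SPG20 contrast the G2/M median was 0.0443 on thinned counts, 0.15 for the mean of cells' CPM, 0.0621 without mitochondrial and ribosomal protein genes in the CPM, 0.10 for every phase, 0.0561 without cluster 2 and 0.0334 if thinned too. The mitochondrial median was −0.0687, −0.42, −0.23, −0.18, −0.0365 and −0.0160 in the same order, and −0.14 in cells of at least 9400 UMIs, with a range from −0.26 (without library 2) to −0.12 (without library 3), and the abscission median 0.0747 for the mean of cells' CPM. On thinned counts signs changed for R3HDM1 (−0.17), LGI1 (−0.21), SPP1 (0.23), SNHG25 (0.0850), ZRSR2 (0.27), PNCK (0.14), MKI67 (−0.00520) and AURKB (−0.0469), and without cluster 2 and thinned for R3HDM1 (−0.24), LGI1 (−0.20), SPP1 (0.17), SNHG25 (0.0233), ZRSR2 (0.27), PNCK (0.0529), MKI67 (−0.00661), CCNB1 (−0.00964) and AURKB (−0.0743).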

Other observations

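The tests in this part were chosen after results were seen, other than those on thinned counts of all clusters. Over all libraries, SPG20 transcripts were highest in S-phase cells, at 52.9 CPM [48.6, 57.4] against 30.5 CPM [28.7, 32.4] in G2/M. By cluster they were highest in cluster 5 (66.4 CPM), which is led by the hindbrain gene EGR2. Library 4 gave 386 of 410 S cells and 154 of 161 cells of cluster 5, but only 50 of 887 G2/M cells. Within library 4 the intervals overlap, at 53.6 CPM [49.2, 58.3] in S and 40.5 CPM [30.3, 53.2] in G2/M. At 9400 UMIs an SPG20 UMI was found in 24.9% [21.6, 28.4] of 646 G2/M cells with a CDC20 UMI and in 31.7% [23.7, 40.6] of 126 without. The intervals of all libraries together overlap, and a difference between libraries was not tested. In library 1 the shares were 19.8% [15.2, 25.2] of 262 cells against 45.2% [27.3, 64.0] of 31, without overlap. With overlapping intervals, they were 28.0% against 28.4% in library 2, 25.9% against 22.7% in library 3 and 45.0% against 33.3% of 6 in library 4. Whether detection of both transcripts is linked stays open.

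Some clusters differed in genes known from parts of the neural tube, named here after their levels had been seen and without a test. Cluster 7 expressed the forebrain and eye field genes HESX1 (126 CPM), FEZF1 (102 CPM) and SIX3 (84.7 CPM), with HOXB2 at 2.59 CPM, while clusters 3 and 5 had HOXB2 at 52.0 and 38.6 CPM and cluster 5 EGR2, a gene of hindbrain segments, at 77.5 CPM. Cluster 4 expressed ANKRD1 (712 CPM), NPPB (108 CPM), ACTC1 (138 CPM) and CNN1 (115 CPM), genes that also respond to actin and YAP signalling, with CYR61 at 557 CPM. Of the 16 cardiomyocyte markers, 3 reached 10 CPM in cluster 4, as 3 did in cluster 7. The sarcomere genes ACTN2 (0.192 CPM) and TTN (0.0962 CPM) were nearly absent from cluster 4, so ACTC1 and NPPB alone do not identify heart muscle cells here.

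Cardiac transcripts were near zero in cells named as cycling cardiomyocytes. Depth is an unlikely cause, as the highest upper limit among 7 cardiac genes was 0.462 CPM, and displaced gene names are too, as 97.6% of ribosomal protein genes (83 of 85) ranked in the top 5%. No cell held UMIs of 8 or more of the 16 fixed cardiomyocyte markers (at most 5 in a cell, upper limit 0.236% of cells), which argues against a sizeable share of cardiomyocytes diluted by other cells. Of 14 neural progenitor genes, 13 reached 10 CPM in all 4 libraries, and a differentiation that gave neural cells and counts from other cells than those labelled would both give this. The G2/M shares were high in 3 libraries and 7.28% in 1, where the labels name 3 G2/M populations and 1 G1 population. Library 4 was not mainly G1 by these calls, with 56.2% of its cells called S and 36.5% G1. Cells of any type chosen by stage can show such shares, so the 2 explanations cannot be told apart here.

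Cells without a CDC20 UMI had fewer other G2/M transcripts. At equal depth the median was still 0.54 [0.46, 0.60], and 0.54 [0.47, 0.59] without the shallow cluster 2 as well, so neither is the whole cause. How much of the 0.91 is due to depth was not tested, since thinning moved cells into the class without a UMI (126 cells against 56). Among cells of at least 9400 UMIs, unthinned and with their classes kept, the median of the G2/M list was 1.04. An earlier point of the cycle stays open. The S-phase list had a median of −0.17 [−0.27, −0.08] on thinned counts without cluster 2, but of 0.00 as reported and 0.53 within library 3. The value within library 3 is not at equal depth, with medians of 36528.5 UMIs in 124 cells and 7134 UMIs in 22. A scoring effect remains possible, since the phase calls use the same list.

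Cells without an SPG20 UMI had a higher share of mitochondrial transcripts among their UMIs. The median was −0.14 [−0.16, −0.11] in cells of at least 9400 UMIs, a cut that does not equalise depth. Before it, the classes stood at medians of 39700 against 31183.5 UMIs. On thinned counts a smaller difference remained, at −0.0687 [−0.09, −0.04]. Thinning redrew the classes, to 161 cells with and 485 without an SPG20 UMI, and these intervals leave out variation between cells. The part of depth thus stays open. A mix of libraries is not the whole cause, as the median was −0.12, −0.11 and −0.66 within libraries 1, 2 and 3. Damaged cells stay open: without cluster 2 and with thinning the median was −0.0160 [−0.05, 0.01], but that cluster is led by mitochondrial genes, so leaving it out removes the difference being tested. No biological explanation was tested.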
